A study of Mus musculus with 4 samples.

How the data were processed

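RNA bound by the Musashi family protein MSI2 was measured by CLIP-seq in mouse intestinal epithelium. In this assay, RNA and protein are joined by ultraviolet light, the protein is precipitated with an antibody, and the attached RNA fragments are sequenced. The 4 libraries were 2 from wild-type mice (WT) and 2 from TRE-Msi2 mice, which carry a doxycycline-inducible Msi2 transgene, all on a C57BL6 background. Per the labels' protocols, the TRE-Msi2 material was total epithelium after 24 hours of doxycycline and the WT material was crypts. By these labels, genotype, tissue fraction and doxycycline differed together, since no doxycycline is recorded for the WT libraries. Crosslinking used 2 pulses of 265 nm light at 400 mJ/cm2, and the complex near 50 kD was cut from the membrane, per the labels. No input, IgG or RNA abundance library was used here, so a peak can reflect the amount of a transcript as well as its binding.

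The submitters' processing notes name cutadapt, TopHat and the mouse builds mm9 and mm10; their versions are not given in the sources used here. The file names describe peak lists called with Piranha after removal of duplicate reads, with the samples of a genotype merged. The authors deposited 1 peak list per genotype, so each list pools 2 libraries and holds no spread between replicates. Each row has a position, a strand and a cell that joins 2 values: a score, which behaves as a read count per 200-nt bin, and a p-value between 0 and 1. Of the single-bin peaks, 99.1% of WT and 96.7% of TRE-Msi2 scores were whole numbers. These per-peak scores are the authors' own. Wider peaks carried fractional scores, as a mean over joined bins would give. A p-value above 0.05 occurred in 2566 WT and 4774 TRE-Msi2 peaks, and in 0 single-bin peaks of either list, so the p-value of a joined peak was not read as a significance. The peak names are numbered up to 12076 in the WT list and 16956 in the TRE-Msi2 list; 15 and 17 of these numbers are skipped in the lists used here.

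The largest coordinates and the contig names (for example a chromosome X peak ending at 169976668) place both lists on mm10, the assembly also called GRCm38. Peaks were therefore assigned with a RefSeq gene table of GRCm38.p6 with 49980 placed genes, of which 21900 are protein-coding. That table gives the start and end of each gene but no strand, exons or untranslated regions, and no genome sequence was used here. The planned shares of peaks in untranslated and coding regions, the search for sequence motifs, and the placement along untranslated regions were therefore not made. Gene spans replaced exons, span length replaced exonic length for matching, and relative position along the gene span, read in the direction of the reads, replaced position along the transcript.

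A gene was counted as having a peak when at least 1 base of a peak fell in its span. Of the peaks, 732 in the WT list and 1026 in the TRE-Msi2 list touched several gene spans, and these cannot be given to a single gene without strand. The strand of the peaks was checked on 16 genes of well-known orientation. In the WT list 85 of 86 peaks and in the TRE-Msi2 list 108 of 109 peaks lay on the transcribed strand; the exception in both lists was the single peak in Lgr5. Of protein-coding genes with more than 1 peak, counting peaks over a single gene, 1473 of 1617 (91.1%) in WT and 2017 of 2272 (88.8%) in TRE-Msi2 had all peaks on the same strand, so some peaks counted for a gene are not from its own transcript.

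Peak lists were compared by overlap of at least 1 base on the same strand. As a reference, each peak was moved at random within the gene it lay in, or along its chromosome when it lay in none, in 100 draws; the planned limit to the same transcript region was not possible. For each of 20 gene lists, the number of members with a peak was placed among 10000 random lists of the same size matched on gene span in 10 classes. Ribosomal protein genes were taken by symbol pattern and mitochondrial genes by chromosome. For members with a TRE-Msi2 peak and no WT peak, random lists were drawn from the genes with a TRE-Msi2 peak, matched on the top TRE-Msi2 score in 5 classes and on the number of peaks (1, 2, or 3 and more). This matched comparison was not planned: it was added after the list counts had been seen, because the BMP and TGF-beta list held 5 WT and 13 TRE-Msi2 members, and it was then applied to all 17 lists that allowed it. These percentiles describe the 2 lists and are not p-values. With 1 pooled list per genotype no difference between genotypes could be tested against replicate spread. Shares carry exact Clopper-Pearson 95% binomial intervals, which cover counting error only. Scores were compared only within a list, since the depth of the libraries is unknown. The lowest score of a single-bin peak was 15 in the WT list and 20 in the TRE-Msi2 list; as read counts these have exact Poisson 95% intervals of 8.40 to 24.7 and 12.2 to 30.9.

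The named genes followed a rule set before the data were examined. Per list, they are the 10 protein-coding genes with the highest peak scores, the 10 with the most peaks, the 10 highest-scoring with no peak in the other list, and up to 4 members of each gene list with the highest scores; further members are named to identify small groups. Some genes that the rule selects, and the count of the smallest list, are not reported here. For the first 3 parts of the rule, only peaks over a single gene were used. The gene lists, the overlap rule and most alternatives were also fixed before the data were examined. The alternatives changed the overlap rule, the use of strand, the score threshold, the length of the TRE-Msi2 list, the merging of peaks, the matching and the background. The quiescence and growth restraint list was written with knowledge of the published study and is not independent evidence. The code was tested on simulated data: 200 of 200 planted peaks were assigned to their gene. In the 5448 genes with a TRE-Msi2 peak, 5 of 200 random 13-gene lists reached the 95th percentile of the matched comparison with nothing planted. With the rate of TRE-Msi2-only genes multiplied by 2 or by 3, up to a cap, 115 and 146 of 200 did. These counts are for the 95th percentile and not for the 99th, at which the lists are counted below. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and bedtools 2.31.1, were used.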

Results

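MSI2-bound RNA was mapped in intestinal epithelium of WT and TRE-Msi2 mice, which allows the transcripts crosslinked to endogenous MSI2 to be set beside those found after the protein is induced. The pooled WT list held 12061 peaks covering 4013 kb, and the pooled TRE-Msi2 list held 16939 peaks covering 6706 kb. Most peaks were a single 200-nt bin (63.2% in WT and 58.8% in TRE-Msi2), and the widest reached 7200 nt and 7800 nt. The median score, in reads per bin, was 19 in the WT list and 24.7 in the TRE-Msi2 list, and the highest was 143 and 124. Each list pools 2 libraries of unknown depth, so no value below has a replicate error and no difference between genotypes was tested against replicates. All positions are on mm10.

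Peaks lay in the Msi2 gene itself in both lists. Msi2, which spans positions 88339382 to 88718306 of chromosome 11, held 6 peaks in the WT list and 7 in the TRE-Msi2 list. Its highest score in either list was at positions 88717287 to 88717486, with 41 reads per bin in WT and 68 in TRE-Msi2. Its paralog Msi1, on chromosome 5, held 1 WT and 3 TRE-Msi2 peaks, and the position of its highest score (115440392 to 115440591) was shared. These peaks do not check the genotype labels, because scores cannot be compared between lists of unknown depth.

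The WT genes with the most peaks and the highest scores included transcripts of absorptive and Paneth cells. Sis and Mgam, the brush-border disaccharidases, held 35 and 23 WT peaks, Apob, the apolipoprotein of chylomicrons, held 17, and the peptidase Dpp4 held 15. St3gal4, a sialyltransferase, held the most of any gene, 40, and Dmbt1, a secreted mucosal glycoprotein, held 16. Erbin held 15, and Clca4b and the kinase Hipk2 held 12 each. The highest WT score of any peak was 143 in Defa34, an alpha-defensin of Paneth cells, followed among the defensins by Defa24 at 97 and Defa17 at 89.5. Alpha-defensins are near-identical copies, so reads may be shared among them. The other genes with the highest scores were Camk1d (108.5), Lars2 (106.5), Sspn (106), Jarid2 (104.7), Rsph3b (104), Zc3h7a (93.7) and Peak1 (91.3). These 7 genes each held no more than 2 WT peaks over spans of 33.4 kb to 421 kb, and in Camk1d, Jarid2, Rsph3b and Zc3h7a the top WT peak lay on the strand opposite to most other peaks of the gene, counted over both lists.

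Of 25 enterocyte genes, 24 held a WT peak, more than in all 10000 random lists matched on gene span. Examples are Apob (top score 81.4), Fabp2 (78), a fatty acid binding protein, Mgam (66) and Dpp4 (66). Of 10 Paneth cell genes, 9 held a WT peak, among them Defa24, Defa17, the lysozyme gene Lyz1 (74.2) and Reg3g (62.3). Of 10 goblet cell genes, 6 did, including the mucosal lectin Zg16 (77.3), Clca1 (37.5), Fcgbp (35.7) and the mucin Muc2 (31), at the 99.8th percentile. Enteroendocrine genes gave 4 of 10, with Chgb at 53, Tac1 at 23, Cck at 19 and Sct at 15. Tuft cell genes gave 1 of 8, Dclk1. Immune genes gave 4 of 13, namely Cd74 (47), Lyz2 (39.6), Ccl5 (29) and Jchain (22). All peaks of Fabp2 and Ccl5 also touched another gene span. Of 11 stromal genes, such as Col1a1 and Vim, 0 held a peak in either list. The WT material is described as crypts, yet 24 of 25 enterocyte genes held a peak there, so how far the tissue fractions differed is not known.

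Stem cell, cell cycle and housekeeping transcripts were also present in the WT list. Of 20 stem cell genes 11 held a WT peak, at the 99.5th percentile of matched random lists, led by Cd44 (63), Olfm4 (57.5), the cotransporter gene Slc12a2 (31.2) and Sox9 (26). The 11 include Lgr5, whose only peak lay on the strand opposite to the gene and is not evidence for its transcript; with Lgr5 not counted, 10 of 20 did, at the 98.6th percentile. Of 30 proliferation genes 12 held a WT peak, at the 99.5th percentile, led by Rb1 (32), Stmn1 (29), Hmgb2 (26.5) and Mki67 (26). The 12 include Rb1, Cdkn1a and Cdkn1b, which restrain the cell cycle, so the count is not one of growth-promoting genes alone. Of 23 epithelial junction and cytoskeleton genes 18 did, with Epcam at 81.6, Cdh17 at 56.6, Dsp at 54.6 and Actg1 at 48.4. Of 30 RNA-binding regulators 23 did, led by the poly(A)-binding protein gene Pabpc1 (54), Msi2 (41), Hnrnpa2b1 (34.5) and the helicase gene Ddx5 (34). Of 23 translation factors 17 did, led by Eif4a2 (47.5), Eef1a1 (40.9), Eif1 (36.8) and Eif4b (35). Of 79 ribosomal protein genes 41 did. The junction, RNA-binding, translation and ribosomal lists each exceeded all 10000 matched random lists. With only genes that hold a peak in either list as background, they stood at percentiles 97.3, 99.9, 99.4 and 55.4. The WT stem cell list, Lgr5 included, stood at 49.3 there, and the WT proliferation list at 91.3. In all, 4 lists in WT and 0 in TRE-Msi2 reached 99 with that background, instead of 10 and 11. The 10 include the stem cell list only with Lgr5 counted. The 4, the 10 and the 11 each include the mitochondrial genes, where 1 wide peak can cover many genes. The 0 follows largely from that background, since 5448 of its 5711 genes held a TRE-Msi2 peak. Because transcript abundance was not measured, these percentiles mix abundance and binding.

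Peaks were found over genes that restrain growth and keep stem cells quiescent. Bmpr1a, a BMP receptor on chromosome 14, held 3 WT and 8 TRE-Msi2 peaks, and all 3 of the WT peaks lay within 3 kb of the end of the gene toward which its reads run. Cdkn1a, the cell cycle inhibitor p21 on chromosome 17, held 2 peaks in each list, with top scores of 25 and 51. Lrig1, a stem cell marker and brake on growth factor receptors on chromosome 6, held 0 WT peaks and 1 TRE-Msi2 peak at 94605407 to 94605606, with a score of 22. These genes were chosen with knowledge of the study, so their peaks are not independent evidence. The map of peaks over these genes and Msi2 shows their places.

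**Figure D1:**
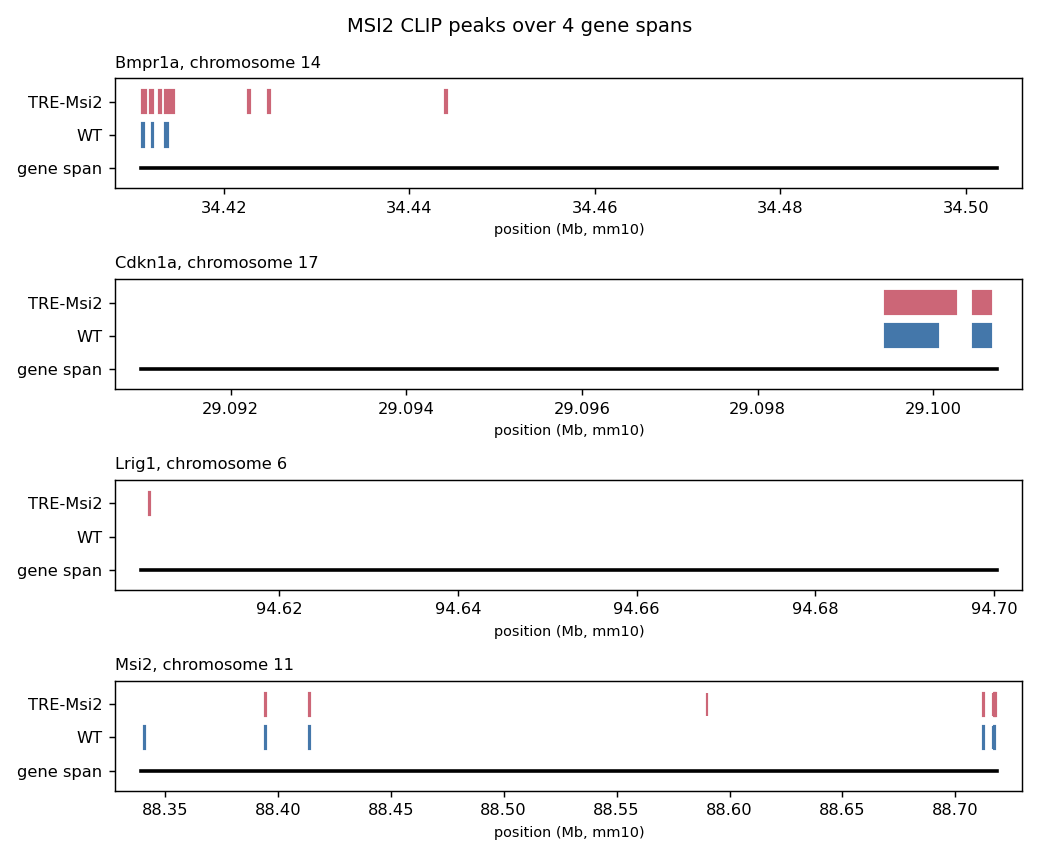
Peaks (coloured blocks, to scale apart from a thin outline) of the WT and TRE-Msi2 lists over the gene spans (black lines) of Bmpr1a, Cdkn1a, Lrig1 and Msi2; the horizontal axis is the position in Mb on mm10. Bmpr1a holds 3 WT and 8 TRE-Msi2 peaks, and Lrig1 holds a single TRE-Msi2 peak.

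In the WT list, 12 of 26 PI3K, Akt and mTORC1 genes held a peak, at the 98.5th percentile, led by Irs2 (34), Pdpk1 (31) and Eif4e (31). Of 20 Wnt genes 10 did, against a random median of 5, led by Ctnnb1 (47.1), Csnk1a1 (37.5), Tcf7 (35.6) and Lrp6 (32); Apc, the tumour suppressor, held 5 peaks. Of 17 Notch genes 5 did, at the 73.5th percentile, with Adam10 at 23, Numb at 17.5 and Jag1 at 17. The WT peaks of Tcf7 and Numb also touched another gene span. Of 18 BMP and TGF-beta genes 5 did, which is percentile 54.2: Bmpr1a, Smad4, Smad5, Smad1 and Smad2. The list named nuclear long noncoding RNA gave 7 of 8, with 16 WT peaks over Neat1 and 2 over Malat1. All WT peaks of the other 5, Kcnq1ot1, Meg3, Norad, Snhg1 and Gas5, also touched another gene span. Where in the cell these RNAs lie was not measured, and the name of the list does not fix it for each member. The mitochondrial genome held 7 WT peaks.

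The TRE-Msi2 list named largely the same cell types. The genes with the most peaks were Mgam (52), Sis (44), St3gal4 (37), Erbin and Arfgef1 (21 each), Dpp4 (20), Apob (19), and Dmbt1, the clathrin heavy chain gene Cltc and 4932438A13Rik (17 each). The highest scores in single genes were in Defa37 (120), Camk1d (119.5), Defa34 (119), Rsph3b (113), the mucin Muc13 (111.8), Lars2 (111), the metabolic enzyme Mdh1 (106.5), the peptidase Anpep (106.5), Jarid2 (106) and Dpp4 (104). The same 24 enterocyte, 9 Paneth, 6 goblet and 4 immune genes as in the WT list held peaks. Enteroendocrine genes gave 5 of 10, tuft cell genes 0 of 8 and stromal genes 0 of 11. RNA-binding regulators gave 23 of 30, translation factors 17 of 23, and both lists were made up of the same members as in WT. Ribosomal protein genes gave 54 of 79, among them Rps27a (61), Rps20 (52) and Rps3a1 (47), and 40 of the 54 were shared with WT. Stem cell genes gave 14 of 20, Lgr5 included, or 13 with Lgr5 not counted, at the 99.9th percentile. Those added to the WT members were Smoc2, Axin2 and Lrig1, each with 1 peak, at scores of 21, 22 and 22. The lowest single-bin TRE-Msi2 score was 20. Lists of TRE-Msi2 genes matched on score and number of peaks had a median of 4 genes without a WT peak, against these 3 (percentile 26.1). Proliferation genes gave 12 of 30, Wnt genes 11 of 20, Notch genes 6 of 17 and PI3K, Akt and mTORC1 genes 11 of 26, the last at the 87.8th percentile. Epithelial junction genes gave 19 of 23, with Krt18 added, and the mitochondrial genome held 6 peaks. The plot of gene lists shows the share of members with a peak.

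**Figure D2:**
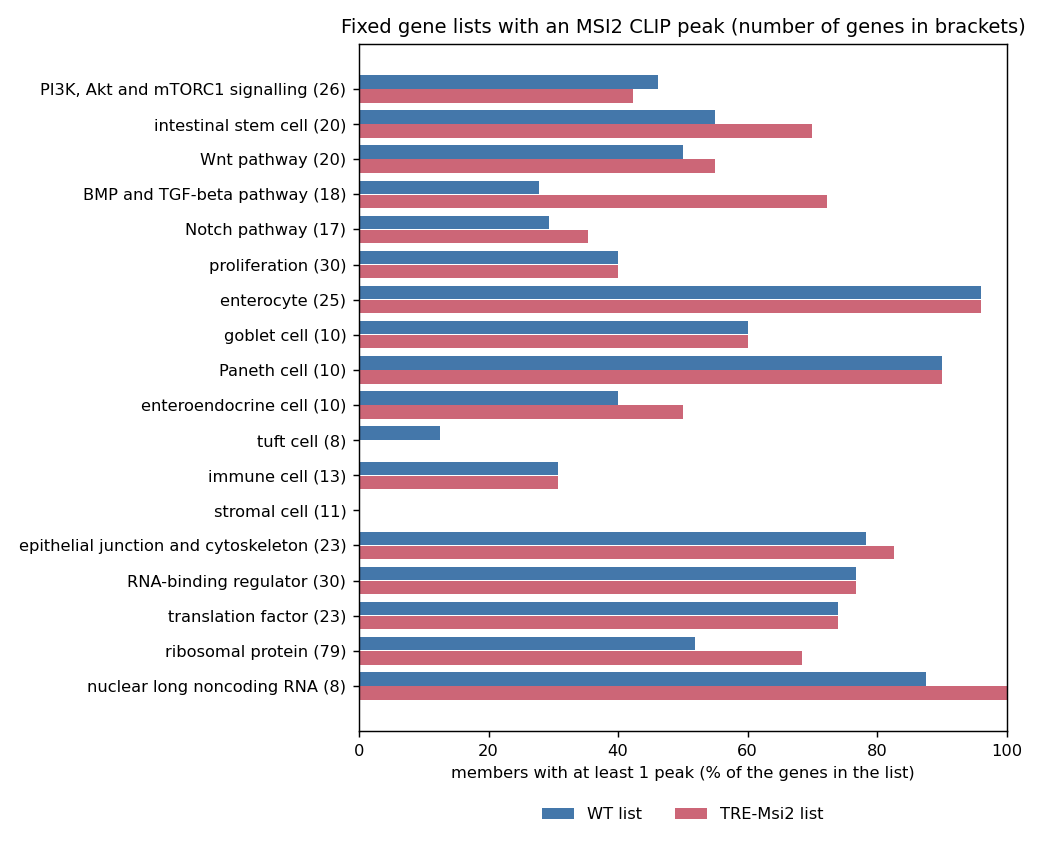
Percentage of the genes in the fixed lists shown (horizontal axis) with at least 1 peak in the WT list and in the TRE-Msi2 list, each a pooled list without replicates; the number of genes in each list is in brackets. Enterocyte and Paneth lists are nearly complete in both, the stromal list is empty in both, and the BMP and TGF-beta list has 5 members in WT and 13 in TRE-Msi2.

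Most WT peaks had a TRE-Msi2 counterpart; the share was lower in the other direction, where the TRE-Msi2 list is longer. Of WT peaks 91.3% (95% interval 90.8% to 91.8%) were overlapped by a TRE-Msi2 peak, against a median of 9.57% (highest draw 10.1%) for peaks moved at random, within their genes or, outside genes, along the chromosome. For WT peaks inside genes alone the share was 90.9%, against a median of 12.9% (highest draw 13.6%). Of TRE-Msi2 peaks 57.6% (56.8% to 58.3%) were overlapped by a WT peak, against a median of 6.48% for moved peaks. Inside genes the shares were 59.0% and 8.60%. Moved peaks could fall anywhere in a gene span, introns included. This reference therefore cannot separate shared binding sites from coverage of the same exons. In the TRE-Msi2 list overlap rose with the score apart from the lowest 10%. From the second lowest 10% of TRE-Msi2 scores to the highest, the share with a WT peak ran from 28.6% to 95.6%, and the lowest 10%, which includes joined peaks with averaged scores, stood at 59.6%. TRE-Msi2 peaks without a WT peak had a median score of 23, against 27 for those with one. Among WT peaks the shares were 92.0% in the lowest 10%, 79.4% in the second lowest and 97.1% in the highest. Classes 8 and 9 of the WT list already stood at 97.3% and 97.0%. Overlap also went with width: 41.5% of single-bin and 80.5% of wider TRE-Msi2 peaks had a WT peak. Among single-bin TRE-Msi2 peaks alone, a division chosen after seeing the data, the share ran from 11.6% in the lowest 10% of scores to 93.2% in the highest. With the TRE-Msi2 list shortened to the WT length by score, 70.4% of WT and 63.5% of TRE-Msi2 peaks were overlapped, and shortened by p-value, 47.0% and 46.6%, against 91.3% and 57.6% for the full lists. Of the 4878 peaks removed by p-value, 4784 were wider than 1 bin.

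**Figure D3:**
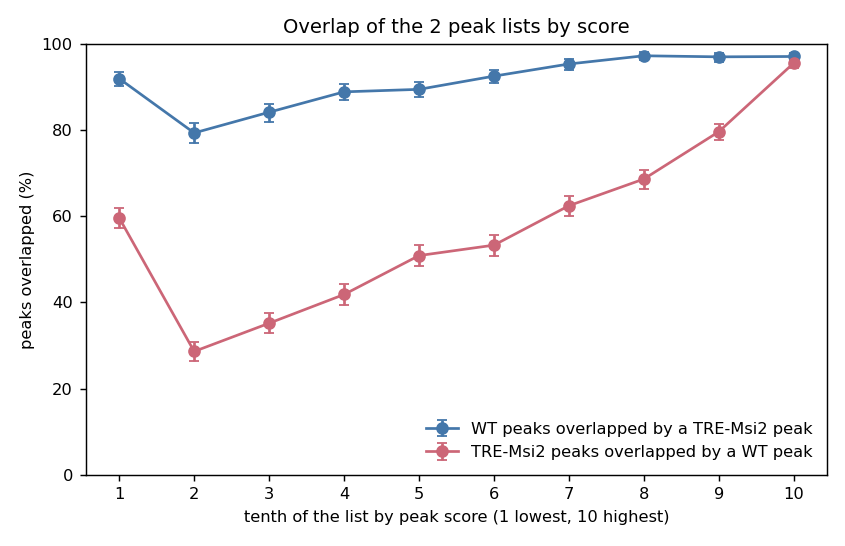
Percentage of peaks overlapped by a peak of the other list on the same strand (vertical axis) in 10 equal classes of each list by peak score (horizontal axis, 10 the highest); bars are exact 95% binomial intervals for counting error. In class 10 of the TRE-Msi2 list 95.6% have a WT peak, and in class 2 28.6% do.

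At the level of genes, 4449 protein-coding genes held a WT peak, 5448 held a TRE-Msi2 peak and 4186 held both. That is 94.1% of the WT genes and 76.8% of the TRE-Msi2 genes. Independent lists of these sizes would share 1107 of the 21900 protein-coding genes. Among the 5711 genes with a peak in either list they would share 4244, which is near the observed number because that background is made of the lists themselves. Genes with peaks had long spans, with medians of 31.3 kb in WT and 29.3 kb in TRE-Msi2 against 17.1 kb over all protein-coding genes.

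Of the 18 BMP and TGF-beta genes, 13 held a TRE-Msi2 peak, of which 8 had no WT peak. These 8 were the receptors Bmpr2, Acvr1b, Acvr2a and Tgfbr1, the inhibitory Smad gene Smad7, and Id1, Id2 and Id3, transcriptional targets of the pathway. Their top TRE-Msi2 scores ran from 16 in Id2 to 33 in Id1, and Acvr2a held 4 peaks and Bmpr2 held 3. Of the 8, only Id1 and Id3 (27) had a top score above 24.7, the median of all TRE-Msi2 peaks. The lowest single-bin TRE-Msi2 score was 20. Lists of TRE-Msi2 genes matched on score and number of peaks had a median of 4 such genes, which put the observed 8 at the 99.8th percentile, the highest of 17 lists. This comparison was added after the counts of 5 and 13 had been seen, so it is not an independent test of this list. The chance that at least 1 of 17 independent lists reaches this is 6.59%, and the percentile fell below 99 in 3 alternatives. It was 92.1 with the upper 50% of each list by score (5 of 7 genes without a WT peak), 98.2 with the TRE-Msi2 list cut to the WT length by p-value (7 of 12), and 98.6 cut by score (5 of 10). The cut by p-value mainly took out wide peaks, since 4784 of the 4878 peaks removed were wider than 1 bin, so it is not a plain change of threshold. The same 24 of 25 enterocyte genes held peaks in both lists, and per the labels tissue fraction and doxycycline differed with genotype. Ribosomal protein genes had 14 without a WT peak, at the 87.5th percentile. RNA-binding regulators had 0 of 23 and translation factors 0 of 17, at the 2.11th and 6.79th percentiles. Enterocyte, goblet, Paneth and immune genes also had 0, and matched lists had medians of 0 or 1 there.

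Some genes held peaks in a single list. The highest-scoring genes with TRE-Msi2 but no WT peaks were Amer1 (55), a negative regulator of Wnt signalling, Rab3c (53), the netrin receptor gene Dcc (50), Klk14 (49), A430033K04Rik (45), the metallothionein gene Mt1 (43), Rhox8 (41.7), Bbx (39), Vta1 (37) and Higd2a (37). Most held a single peak; Rab3c and Dcc held 3 each. The highest-scoring genes with WT but no TRE-Msi2 peaks were Fbxo25 (31), Rasgrf2 (29), D430019H16Rik (27), Nfia (24), Lingo2 (24), the tachykinin gene Tac1 (23), and Rbbp5, Slc28a2b, Lag3 and Hs3st4 (22 each). Of these only Nfia held 2 peaks. Over both rankings, gene spans ran from 0.917 kb in Higd2a to 1255 kb in Lingo2. Genes were assigned without strand, so a lone peak in a long span may not come from the transcript of that gene. From the fixed lists, Akt1, Rictor, Rheb, Cdkn1b, Rpl10a and Dclk1 also held WT peaks alone, with top scores from 15 to 20, where the lowest single-bin WT score was 15. In all, 263 genes held only WT peaks and 1262 only TRE-Msi2 peaks; with the TRE-Msi2 list cut to the WT length these were 656 and 727 by score, and 839 and 1172 by p-value. Neither direction has a replicate check, and per the labels tissue fraction and doxycycline differed with genotype.

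Peaks gathered toward the end of genes. Along protein-coding gene spans read in the direction of the reads, 48.2% of WT peaks (47.1% to 49.3%) and 43.2% of TRE-Msi2 peaks (42.2% to 44.1%) fell in the last 10% of the span. In genes of at least 10 kb, 39.0% of WT peaks (37.8% to 40.2%) and 33.2% of TRE-Msi2 peaks (32.3% to 34.2%) lay in the last 2 kb, where even placement would give 5.59% and 5.56%. In the first 2 kb the shares were 4.78% and 4.68%. Even placement counts introns as well as exons. The excess at gene ends therefore cannot separate a preference of MSI2 from the coverage of spliced RNA. The intervals of the 2 lists did not overlap for the last 2 kb, but they leave out the spread between replicates. TRE-Msi2 peaks that had a WT peak lay there in 39.4% of cases (38.1% to 40.7%), and those without in 24.9% (23.6% to 26.3%). WT peaks that had a TRE-Msi2 peak lay there in 38.8% of cases (37.6% to 40.1%), and those without in 40.6% (36.6% to 44.6%). Over all peaks, 66.6% of WT and 68.1% of TRE-Msi2 peaks lay in protein-coding genes, which cover 37.9% of the chromosomes. Genes of long noncoding RNAs took 2.94% and 2.92%, and 26.1% and 25.3% lay outside every gene.

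**Figure D4:**
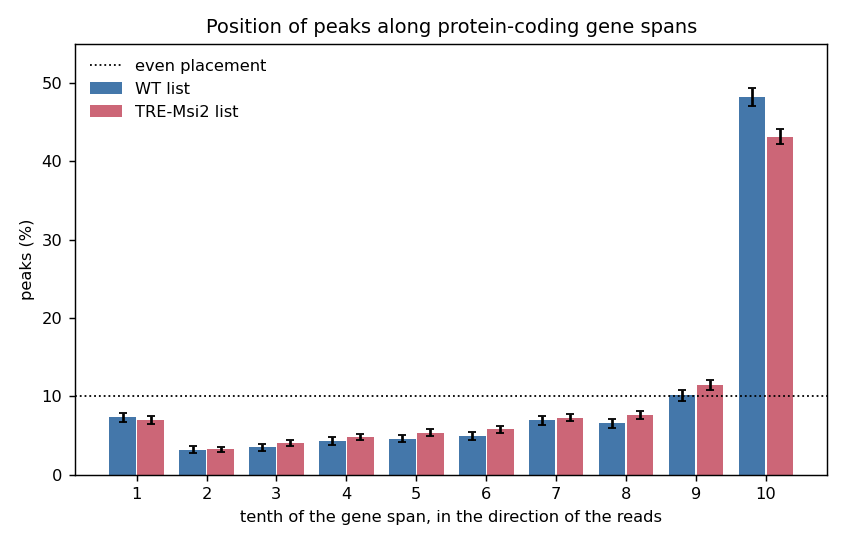
Percentage of peaks (vertical axis) in 10 equal parts of the gene span in the direction of the reads (horizontal axis) for peaks over a single protein-coding gene; bars are exact 95% binomial intervals for counting error and the dotted line is even placement at 10%. The last part holds 48.2% of WT and 43.2% of TRE-Msi2 peaks.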

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

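Of the tests in this part, the comparison of place within classes of score, over all and over single-bin peaks, the rise of overlap among single-bin peaks, and the enterocyte test of the BMP genes were chosen after the result was seen. The matched comparison of the BMP genes was devised after their counts had been seen, though before its percentile was, and the demand that the percentile hold under all alternatives was added after it was seen. The values given first are mostly signals that the comparisons of genes did not use. The exceptions are small RNA peaks that also touched a protein-coding span, which were counted for that gene, and those on the mitochondrial genome. With protein-coding genes put before small RNA genes, the share of peaks in protein-coding genes was 67.4% in WT and 68.6% in TRE-Msi2, instead of 66.6% and 68.1%. Outside every gene span lay 3142 WT and 4280 TRE-Msi2 peaks; the highest-scoring WT one, on chromosome 6 at positions 49236402 to 49236601, had 103 reads per bin and was overlapped by a TRE-Msi2 peak. Over small RNA genes lay 351 WT and 404 TRE-Msi2 peaks, among them 153 and 142 over snRNA genes and 98 and 153 over nuclear tRNA genes. On unplaced contigs lay 9 WT and 11 TRE-Msi2 peaks.

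TRE-Msi2 peaks without a WT peak numbered 7186, and the 3998 of them in protein-coding genes of at least 10 kb lay less often near gene ends than the 5376 with one; WT peaks without a TRE-Msi2 peak did not (40.6% against 38.8%). A difference in depth and calling threshold would give a rise of overlap with score. The share with a WT peak was 35.9 percentage points greater in the highest 10% of TRE-Msi2 scores than in the lowest 10%, which includes joined peaks with averaged scores. Among single-bin peaks, where width is equal, it was 81.5 points greater. Weak sites added with genotype, tissue fraction or doxycycline would give such a rise too, so it does not single out depth and threshold. Within 10 classes of score, peaks without a WT peak were in the last 2 kb less often by 15.8 points (-15.8 ± 1.17, counting SE), lower in 10 of 10 classes, and single-bin peaks alone gave -15.9 ± 1.83, which argues against a low score alone setting their place, while depth and threshold stay open. More background reads in the TRE-Msi2 libraries stay open, since such peaks lay opposite to the other peaks of their gene 1.39 times as often (6.72% against 4.82%), which is under the ratio of 2 set for that explanation and above equality. Genotype, tissue fraction and doxycycline, as labelled, cannot be told apart, and among the highest 10% of scores 4.43% had no WT peak.

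The 8 BMP and TGF-beta genes with TRE-Msi2 peaks alone were weighed because this list had 5 WT and 13 TRE-Msi2 members. All 8 had a TRE-Msi2 peak over no other gene, which argues against peaks of neighbouring genes. The 99.8th percentile among lists matched on score and number of peaks passed the bound of 99 first set for excluding depth and threshold, but that bound ignored that this list was picked as the most extreme of 17 (chance 6.59%), and the percentile ranged from 92.1 to 99.8 over the alternatives, so this explanation stays open. The enterocyte test could not judge whether the TRE-Msi2 material held more villus cells, because 0 enterocyte genes had a TRE-Msi2 peak alone while matched lists had a median of 0. The sizes of the peak scores of cell type genes were not weighed for this explanation, since the depth of the lists is unknown. Induced MSI2 binding these transcripts may be a further account and was not tested apart from the tissue fraction or the doxycycline itself.

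High-scoring isolated peaks in long genes such as Camk1d and Jarid2 were weighed as possible reads from other loci. Among the 100 highest WT peaks in protein-coding genes, 22 lay in genes of at least 30 kb with no more than 2 peaks, and all 22 were overlapped by a TRE-Msi2 peak. Of the 13 whose gene had other peaks in either list to compare with, 6 (46.2%, 95% interval 19.2% to 74.9%) lay on the strand opposite to most of them, against 8.81% of all WT peaks in such genes; in the TRE-Msi2 list 2 of 6 did (33.3%, interval 4.33% to 77.7%), against 13.9%. This is consistent with reads from repeated copies or embedded small RNA genes, a hypothesis that sequence would be needed to test. No biological explanation was tested for this pattern.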

How the results depend on the processing

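Each choice was changed alone. The share of WT peaks with a TRE-Msi2 peak (91.3%) became 68.5% with overlap of at least 50% of both peaks, 93.4% with strand ignored, 69.0% with the upper 50% of each list by score, 47.0% with the TRE-Msi2 list cut to the WT length by p, and 70.4% cut by score. The share of TRE-Msi2 peaks with a WT peak (57.6%) became 48.8%, 59.0%, 47.3%, 46.6% and 63.5% under the same settings. Both shares stayed within their counting intervals when peaks within 50 nt counted or were merged and without the mitochondrial genome. Of the 4878 TRE-Msi2 peaks removed by p, 4784 were wider than 1 bin. With the upper 50% of each list, protein-coding genes with peaks numbered 2922 in WT, 3629 in TRE-Msi2 and 2503 in both, the shares of peaks in protein-coding genes were 70.5% and 70.0%, and the share of WT peaks in the last 2 kb was 41.5%. Cutting the TRE-Msi2 list by score left 727 genes with TRE-Msi2 peaks alone, from 1262, and the genes with WT peaks alone rose from 263 to 656, to 839 with the cut by p, and to 419 with the upper 50%. The genes that independent lists would share were 1107 with all protein-coding genes as background, from 4244. At or above the 99th percentile stood 10 of the 19 lists with protein-coding members in WT and 11 in TRE-Msi2. With genes holding a peak in either list as background these were 4 and 0, by construction of that background. The 10 include the stem cell list only with Lgr5 counted, and the 10, the 11 and the 4 include the mitochondrial genes. The percentile of the BMP and TGF-beta list fell below 99 to 92.1 with the upper 50% of lists, 98.2 with the cut by p and 98.6 with the cut by score; the cause was not tested. Of the other values, 158 stayed within 1.5 times the main count, within the counting interval or on the same side of the threshold, 14 left that range, and the percentile of the proteasome genes fell below 99 in 2 settings. With the upper 50% of each list, PI3K genes in WT fell from 12 to 7, stem cell genes in TRE-Msi2 from 14 to 9, BMP and TGF-beta genes from 5 and 13 to 2 and 7, Notch genes from 5 and 6 to 2 and 3, enteroendocrine genes in WT from 4 to 2 and ribosomal protein genes in WT from 41 to 27. With peaks over a single gene, noncoding RNAs fell from 7 and 8 to 2 and 2 and mitochondrial genes from 33 and 35 to 4 and 1, the last also 1 with the cut by p. The rise of overlap with score went from 35.9 to 81.5 points with single-bin peaks. The cut by score, the limit to peaks over a single gene, the midpoint and priority rules for gene classes, Lgr5 not counted, single-bin peaks alone, the alternatives for proteasome genes, and every alternative of the matched BMP comparison were chosen after seeing the data. Not run were exon-only counting, transcript region priority, largest overlap, motif controls and transcript choice, which need exons or sequence, strand ignored for gene classes, since gene spans carry no strand, and leaving out replicates. No paired analysis was possible because each list pools the replicates of a genotype. Unknown depth limits every statement on peaks found in a single list.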

Other observations

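All 8 gene families here were chosen after the fixed lists had been examined. Of 99 genes named as oxidative phosphorylation subunits, 43 held a WT and 54 a TRE-Msi2 peak, more than all 10000 random lists matched on gene span; Atp5g3 held 3 peaks in each list, with top scores of 57.5 and 54.3. Of 40 proteasome subunit genes, 12 held a WT peak and 21 a TRE-Msi2 peak, and the 9 without a WT peak, among them Psmc1, Psmc2 and Psma5, stood at the 99.4th percentile of lists matched on score and number of peaks. The chance that at least 1 of 8 independent families reaches this is 7.80%, and the percentile was 47.2 with the upper 50% of each list by score and 98.8 with the TRE-Msi2 list cut by score. Of 32 splicing factor genes named Srsf, Sf3 or Snrp, 15 held a WT and 17 a TRE-Msi2 peak, and 3 of the 17 lacked a WT peak, at the 2.12th percentile. Of 347 solute carrier genes, 107 held a WT and 126 a TRE-Msi2 peak. Of 397 zinc finger genes named Zfp, 90 held a WT and 113 a TRE-Msi2 peak, at the 66.4th and 75.3rd percentiles of lists matched on span, and of 80 cytochrome P450 genes 17 and 20 did, at the 43.7th and 33.2nd. Of 28 alpha-defensin genes, 24 held a peak in each list. Of 1110 olfactory receptor genes 2 held a peak in each list against a random median of 45 and 57.

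Xist and Neat1 were singled out after their values were seen. Xist, the noncoding RNA of the inactive X chromosome, held 0 WT peaks and 4 TRE-Msi2 peaks. All 4 lay on the minus strand and also touched another gene span, and their top score was 30. Why the lists differ there was not tested, and the sex of the mice was not part of the sample information used here. Peaks on chromosome Y numbered 80 in the WT list and 111 in the TRE-Msi2 list, so they were not fewer in the list with Xist peaks. These counts do not settle the sex of the mice. Neat1 held 16 WT and 20 TRE-Msi2 peaks.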
